A study of Mus musculus with 13 samples.

How the data were processed

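Chromatin immunoprecipitation and sequencing of H3K9me3 and H3K27me3 was carried out on inducible Setdb1 knockout J1 mouse embryonic stem cells with or without 2.5 µM tamoxifen. Per the labels' protocols, chromatin was sonicated, precipitated with antibody and sequenced on an Illumina HiSeq, and the solvent of tamoxifen was used as the control treatment. The labels describe 13 samples, of which 8 had a file here. Groups came from the titles. These were H3K9me3 untreated (n = 4), H3K27me3 untreated (n = 2), H3K27me3 with tamoxifen (n = 2), input untreated (n = 3) and input with tamoxifen (n = 2). The 5 inputs were not analysed here. H3K9me3 replicate 4 has the entry none as its antibody, and it was kept in its group by its title. The first library of each group carries no replicate number and was numbered 1, so the numbers do not pair libraries of different groups.

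The authors deposited 1 peak list per library, with 3 columns that hold the chromosome, start and end of each peak. No score, height, p-value or read count is in the lists, so peaks have no ranking by strength and the depth of each library is unknown. Per the submitters' processing notes, the tools were Bowtie 0.12.7 and MACS2 on build mm9. The notes name MACS2 2.0.10 for replicate 1 of each group and MACS2 2.1.0 for the others, and these sets of libraries are treated as the first and second batch. The calling mode, the threshold and the control used for calling are not given in the sources used here. These settings and the read depth both change how many peaks are called and how wide they are, so peak numbers of different libraries are not a measure of the amount of a mark.

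Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. Touching or overlapping peaks of the libraries compared were merged into regions, and a library held a region if at least 1 bp of it lay in a peak. H3K27me3 regions were kept if all 4 libraries held them, gained if both tamoxifen libraries and no untreated one did, and lost in the reverse case. The H3K9me3 consensus was the set of regions held by all 4 H3K9me3 libraries. Identical peaks were counted in each pair of lists, and no pair shared more than 1, so no list is a copy of another. Every library was counted as its own sample, which this check cannot show. Positions are printed counting from 1 on mm9.

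Libraries were compared by two-sided exact permutation tests of their group means. With 2 libraries against 2 the smallest p is 0.333, and with 4 against 2 it is 0.133. Overlap by chance was estimated by circular shifts of 1 set within each chromosome, with 1000 shifts for pairs of libraries and for width classes and 10000 for the co-occurrence of the marks. Shares of regions were compared by two-sided Fisher's exact tests with Woolf's 95% interval of the odds ratio. Tests over chromosomes were adjusted by the Benjamini-Hochberg method over the chromosomes of each comparison. Intervals of single shares are Clopper-Pearson at 95%, and the limit for a count of 0 is 3 counts of the total. The code that assigns regions was run on simulated peaks, where all of 10124 kept, 1736 gained and 856 lost planted regions among 17030 were recovered. Every planted peak kept the middle of its region, and no peak was missed or added. Full recovery therefore followed from the design, and it checks the code, not how well classes are assigned in real lists. On simulated placements of 5446 regions the circular shift test called 2 of 100 random placements, and 100 of 100 in which 50% of overlaps were avoided, with 200 shifts each. These placements were uniform and independent along the chromosomes. They do not show how often the test calls regions that cluster as real ones may.

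Groups, the tests of the peak numbers, overlaps, region classes, consensus and co-occurrence, and their alternatives other than those named next were chosen before the data were examined. The comparisons by chromosome, the coverage of wide kept regions, the list of regions with both marks, the split by width within batches, the block by batch with sign flips and the alternatives that rank peaks by width or leave out chromosome 8 or 1 were added after it. The planned rule named 10 regions per class, by score and by width. As the lists hold no score, the 10 widest per class were taken, and the stricter thresholds meant to rank peaks by score were replaced by rankings by width. Alternatives were merging over 1 kb, a cover of at least 50%, peaks of at least 500 bp, the chromosomes 1 to 19 and X, the consensus in at least 2 libraries, each batch alone, leaving out each library in turn, the wider 50% of each list, an equal number of widest peaks, and leaving out chromosome 8 or 1.

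No annotation of mm9 was used here. The gene table at hand follows GRCm38.p6, so regions were not assigned to genes, and the planned comparisons at transcription start sites and over gene lists were not run. That table served only to list the chromosomes of the Hox genes.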

Results

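Mouse embryonic stem cells of the J1 line carrying an inducible knockout of Setdb1, a histone H3 lysine 9 methyltransferase, were profiled by chromatin immunoprecipitation and sequencing for 2 repressive histone marks. H3K9me3 is the mark that Setdb1 deposits, and H3K27me3 is the mark of the Polycomb repressive complex. Tamoxifen at 2.5 µM was used to ablate Setdb1, and cells without tamoxifen are called untreated here. Peak lists came from 8 libraries, made up of 4 of H3K9me3 in untreated cells, 2 of H3K27me3 in untreated cells and 2 of H3K27me3 after tamoxifen. The 5 input samples and H3K9me3 after tamoxifen were not analysed here, and the ablation of Setdb1 could not be checked from these lists. Each list gave peak positions alone on mouse build mm9, so the read depth is unknown and no peak has a height. The H3K9me3 lists held 18037, 29410, 42725 and 33743 peaks in replicates 1 to 4. The H3K27me3 lists held 7041 and 17094 peaks in untreated cells, and 15116 and 22265 after tamoxifen. Replicate 1 of each group belonged to a first batch and the other libraries to a second one. Nothing in the labels says that the libraries came from separate cultures, so p-values of group means measure only the spread between these samples, which may be technical. Fisher's exact tests and circular shifts count regions in these lists, and their p-values do not measure spread between samples.

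**Figure D1:**
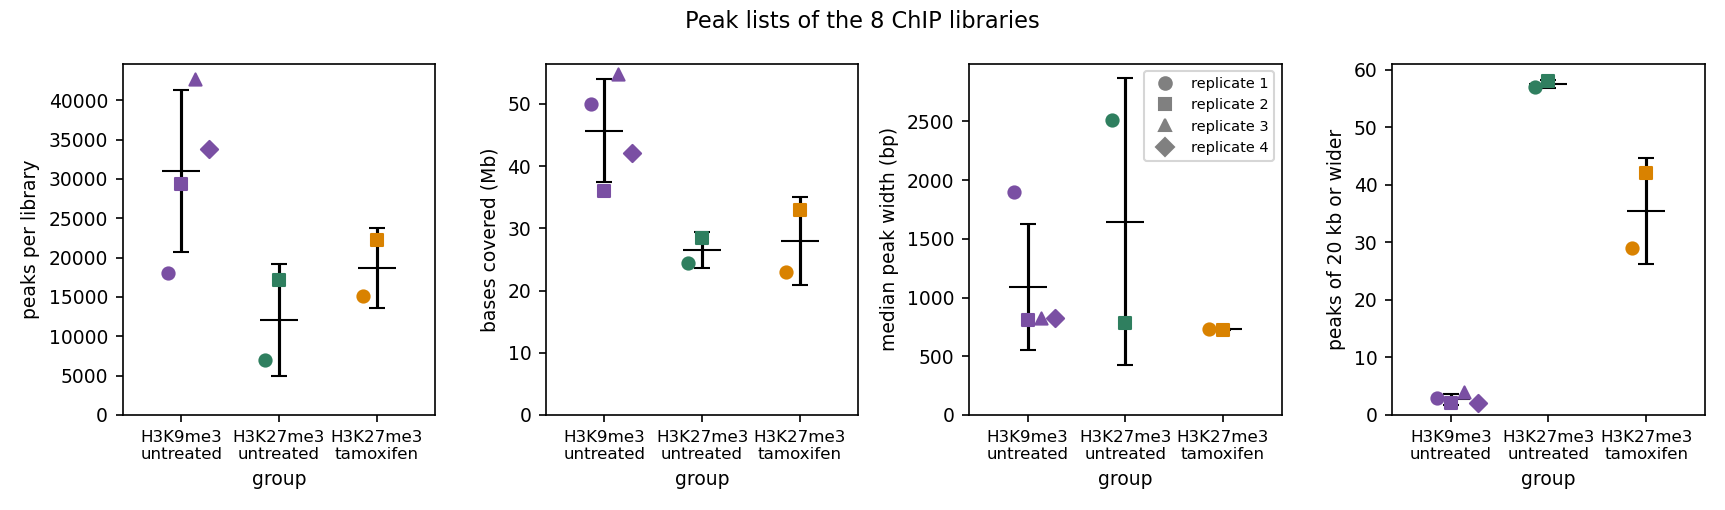
Number of peaks, bases covered in Mb, median peak width in bp and number of peaks of 20 kb or wider for each of the 8 libraries. Points are libraries, marked by replicate, and black lines give the group mean and SD. Peaks of 20 kb or wider numbered 57 and 58 in the untreated H3K27me3 libraries, 29 and 42 after tamoxifen, and 2 to 4 in the H3K9me3 libraries.

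The first question was where the H3K9me3 regions of untreated cells lie. Merging the 4 lists gave 52168 regions, of which 10815 held a peak in all 4 libraries and are called the consensus. Consensus regions covered 49.1 Mb with a median width of 3351 bp, while the 23493 regions found in a single library had a median width of 445 bp. Merging peaks of several lists widens regions, so part of this contrast follows from the definition. The widest consensus region, on chromosome 10 from 82886839 to 82949972, spanned 63134 bp and was covered over 79.6% to 87.4% of its length in the 4 libraries. A neighbouring region of 30228 bp, from 82855524 to 82885751 on the same chromosome, had rank 4. The second widest lay on chromosome 4 from 155508447 to 155558177, at 49731 bp, with 65.6% to 82.4% covered. On chromosome 9 a region of 39373 bp from 3000007 to 3039379 was covered over 97.3% by replicate 1 and over 23.5% to 26.3% by the other 3 libraries. The fifth, on chromosome 6 from 37711455 to 37736681, measured 25227 bp. The other 5 of the 10 widest consensus regions lay on chromosomes 8, 17, 3, 10 and 18 and measured at least 22670 bp.

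Pairs of H3K9me3 libraries shared bases with a Jaccard index of 0.399 ± 0.101 (SD, 6 pairs). The 3 pairs among replicates 2, 3 and 4 gave 0.478, 0.499 and 0.498, and the pairs with replicate 1 gave 0.302 to 0.312. Peaks of one H3K9me3 library overlapped another 11.99 to 23.1 times as often as after circular shifts. Replicate 1 decided much of the consensus, because 7613 regions had a peak in the other 3 libraries and none in replicate 1. Without it, 19974 regions were shared by the remaining 3.

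The second comparison set both marks side by side in untreated cells. H3K9me3 libraries had more peaks and fewer very wide ones than H3K27me3 libraries. H3K9me3 libraries held 30979 ± 10256 peaks over 45.7 ± 8.30 Mb (SD, n = 4), and H3K27me3 libraries held 12067.5 ± 7109 peaks over 26.5 ± 2.87 Mb (SD, n = 2). Peaks of 20 kb or wider numbered 2.75 ± 0.957 per H3K9me3 library and 57.5 ± 0.707 per H3K27me3 library. All H3K9me3 libraries lay above all H3K27me3 libraries in peak number and covered length, and below them in peaks of 10 kb or wider, at 136.5 ± 77.3 against 283 ± 28.3. Each of these 3 comparisons gave a two-sided exact permutation p of 0.133, the smallest that 4 libraries against 2 allow, so none could reach 0.05.

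Both marks occupied almost separate parts of the genome. Of the 5446 regions with H3K27me3 in both untreated libraries, 37 overlapped the H3K9me3 consensus, which is 0.679%, against 212.8 ± 15.6 (SD) in 10000 circular shifts within chromosomes. The observed overlap was 5.75-fold below that chance level (two-sided permutation p = 0.0002, the smallest the shifts can give). With a consensus of at least 2 of the 4 H3K9me3 libraries, the overlap was 0.310 times chance. Over all peaks of single libraries, those with tamoxifen included, it was 0.119 to 0.488 times chance, nearest to chance with H3K9me3 replicate 3. Across single libraries, the Jaccard index between marks was 0.000534 to 0.00312, and between H3K27me3 libraries 0.418 to 0.591. The deficit was of similar size in regions of 1 to 3 kb, where 10 of 1944 overlapped, and in regions of 3 kb or wider, where 26 of 3327 did (two-sided permutation p = 0.002 in each, the smallest that 1000 shifts can give). Among the 175 regions under 1 kb 1 overlapped where 4.03 were found by chance, 0.248 times that level against 0.182 and 0.170 in the wider classes, and at these counts the permutation p by the shifts was 0.194. Regions are not independent replicates, so these p-values describe placement in the genome, not variation between cultures.

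**Figure D2:**
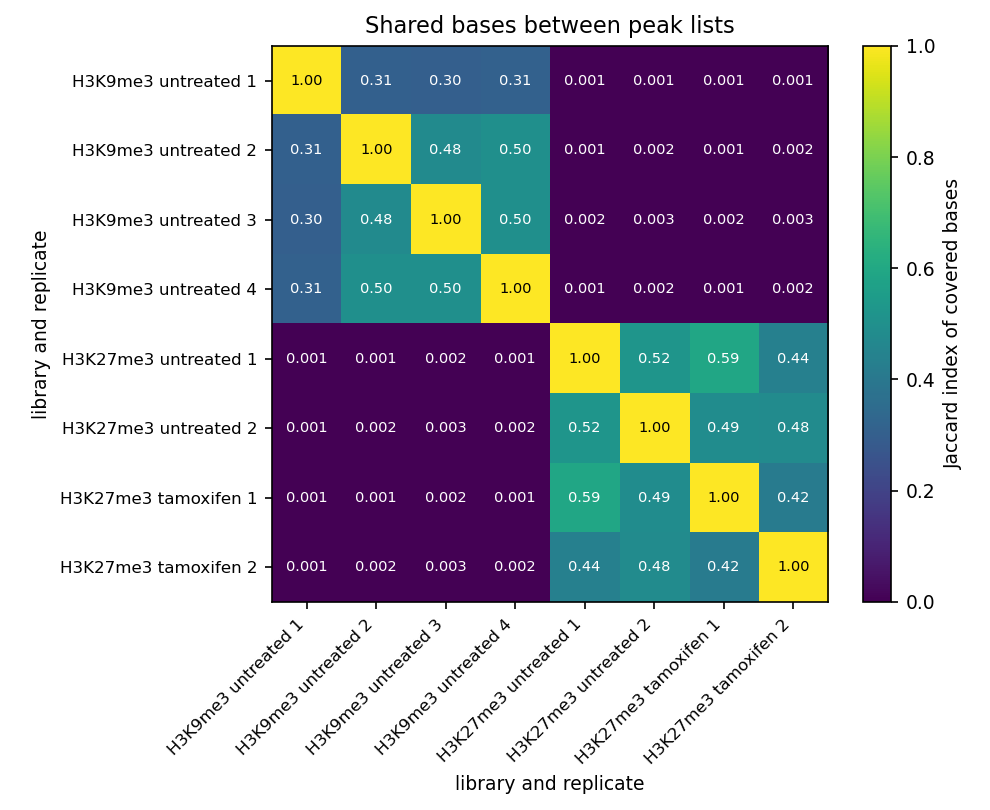
Jaccard index of covered bases (shared bases over bases covered by either list) for every pair of the 8 libraries, by group and replicate. Pairs of the same mark lie between 0.302 and 0.591, and pairs of different marks at 0.00312 or below.

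**Figure D3:**
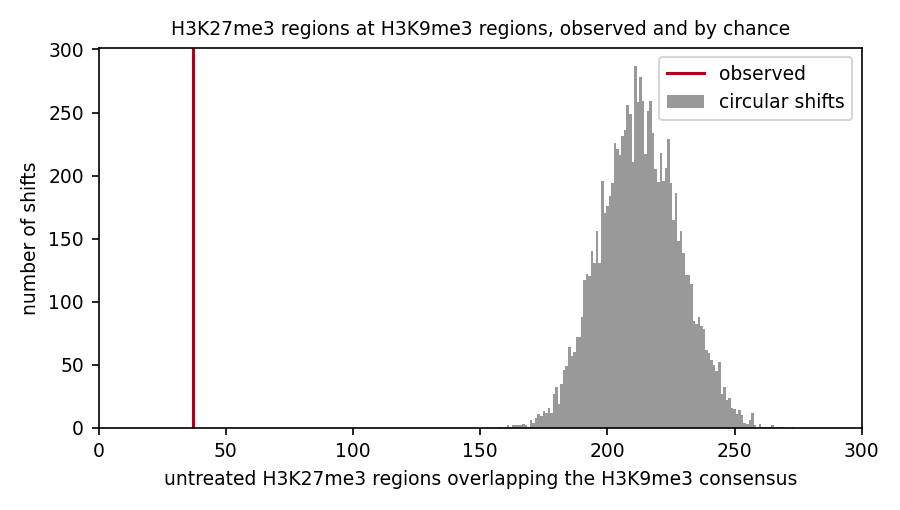
Number of untreated H3K27me3 regions that overlap the H3K9me3 consensus (horizontal axis) in 10000 circular shifts (grey bars, number of shifts), with the observed 37 as a red line. The shifted counts run from 153 to 273.

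The 37 regions with both marks were examined after their number was known. A median of 1266 bp in each was shared by both marks, and 36 of the 37 also overlapped H3K27me3 peaks of both tamoxifen libraries. This is near the share over all merged H3K27me3 regions held by both untreated libraries. Of those, 4841 were held by both tamoxifen libraries, 198 by tamoxifen replicate 1 only, 154 by tamoxifen replicate 2 only and 89 by neither. The largest shared stretch, 11060 bp, lay in a region on chromosome 11 from 11920834 to 11942526. The next 4 by shared bases lay on chromosome 9 from 91261178 to 91288674 (6552 bp), chromosome 2 from 174122050 to 174126899 (4850 bp), chromosome 11 from 3092062 to 3097057 (3986 bp) and chromosome 17 from 39979978 to 39983588 (3611 bp). No positions prone to false peaks were removed from the lists, and the inputs were not analysed. Shared stretches, like regions of the consensus, may therefore include places where any library gives peaks.

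Chromosomes differed in their share of each mark, a comparison chosen after the data were seen. Chromosome 11 held 4.13% of the H3K9me3 consensus regions and 8.12% of the untreated H3K27me3 regions (odds ratio 0.488, 95% interval 0.426 to 0.559, Fisher's exact test adjusted p = 2.29e-23 over 21 chromosomes). Chromosomes 2, 7 and 19 also held a lower share of H3K9me3 regions. Chromosomes 1, 3, 6, 10, 13, 14 and 16 held a higher one, with the highest odds ratio on chromosome 13, at 6.11% against 3.95% (odds ratio 1.58, interval 1.35 to 1.85, Fisher's exact test adjusted p = 3.05e-08).

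The central comparison of the design asked what happened to H3K27me3 when Setdb1 ablation was induced. The 4 H3K27me3 lists merged into 31723 regions, and 4841 of them held a peak in all 4 libraries. These kept regions covered 28.4 Mb with a median width of 4639 bp, and no region outside this class was wider than 9694 bp. A further 693 regions, of 0.799 Mb in all and 1036 bp at the median, held a peak in both tamoxifen libraries and in neither untreated one, and are called gained. The reverse class, called lost, had 89 regions with a median of 1344 bp. Most other regions, 21063 in number, were found in a single library.

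The 4 widest kept regions lay on 4 chromosomes. They ran on chromosome 11 from 96119727 to 96245840 (126114 bp), on chromosome 15 from 102751578 to 102873574 (121997 bp), on chromosome 6 from 52109488 to 52228602 (119115 bp) and on chromosome 2 from 74485081 to 74554429 (69349 bp). In these 4 regions the untreated libraries covered at least 94.5% of the bases and the tamoxifen libraries at least 90.9%. The region on chromosome 2 was followed after 4449 bp by the ninth widest, from 74558879 to 74607186 (48308 bp). Ranks 5 to 8 lay on chromosome 2 from 33452720 to 33505770, chromosome 7 from 77465937 to 77518021, chromosome 13 from 78302854 to 78352939 and chromosome 8 from 59786234 to 59835758. The tenth, on chromosome 11 from 96025110 to 96071013, lay before the widest in coordinate order.

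Gained regions were narrow. The widest, on chromosome 15 from 103367127 to 103371671 (4545 bp), was covered in full by tamoxifen replicate 1 and over 37.1% by replicate 2. The next 3, on chromosome 8 from 26560772 to 26564827 (4056 bp), chromosome 11 from 108752740 to 108756406 (3667 bp) and chromosome 8 from 123821688 to 123825061 (3374 bp), were covered in full by replicate 2 and over 30.3%, 4.39% and 19.2% by replicate 1. The widest lost region, on chromosome 5 from 120132552 to 120138087 (5536 bp), was covered in full by untreated replicate 1 and over 4.06% by replicate 2. The next lost regions were on chromosome 11 from 78629724 to 78634332 (4609 bp) and on chromosome 18 from 7628337 to 7632318 (3982 bp). Among gained regions 47.5% were under 1 kb, and among kept regions 0.372%. Narrowness was not particular to gained regions, because the other classes held by exactly 2 libraries had median widths of 882 to 1344 bp, against 1036 bp for gained ones.

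Gained regions outnumbered lost ones 7.79 to 1, but this excess did not separate the treatment from other divisions of the 4 libraries. Dividing them by batch gave 2296 regions found only in the second batch and 204 found only in the first. The remaining crossed division gave 532 and 65. The tamoxifen lists were also longer, at 18690.5 ± 5055 peaks (SD, n = 2) against 12067.5 ± 7109 in untreated cells (n = 2, two-sided exact permutation p = 0.667, where 0.333 is the smallest possible). The difference of 6623 peaks was 1596.5 without untreated replicate 1 and 11649.5 without untreated replicate 2. The ratio of tamoxifen to untreated peaks was 2.15 in the first batch and 1.30 in the second. Within the first batch 7351 regions were gained and 742 lost, and within the second 12380 and 7048. With the 7041 widest peaks of each H3K27me3 library, an alternative chosen after the data were seen, 128 regions were gained and 164 lost. Leaving out 1 library leaves 1 list in its group and by construction raises the counts of both gained and lost regions. The same holds within a batch, where each state has 1 list. Leaving out untreated replicate 1 gave 892 gained and 6003 lost, and leaving out untreated replicate 2 gave 2067 and 441. Without tamoxifen replicate 1 the counts were 11847 and 298, and without tamoxifen replicate 2 they were 4977 and 245.

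Pairs of an untreated and a tamoxifen H3K27me3 library shared bases as much as pairs of the same state. Their Jaccard indices were 0.435 to 0.591 (4 pairs), against 0.520 for the untreated pair and 0.418 for the tamoxifen pair. Both same-state pairs join libraries of different batches. Mixed pairs across batches gave 0.435 and 0.488. Those within a batch gave 0.591 in the first and 0.483 in the second. Tamoxifen and untreated libraries covered 27.9 ± 7.05 and 26.5 ± 2.87 Mb (SD, n = 2 each, two-sided exact permutation p = 1.0).

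The widest H3K27me3 domains were less completely covered after tamoxifen, in a comparison chosen after the data were seen. Kept regions were merged from the same lists and chosen here by merged width, so the lists with the widest peaks help to set their borders. Peaks of 20 kb or wider numbered 57 and 58 in the untreated lists and 29 and 42 with tamoxifen, so this choice may favour untreated coverage. In the 112 kept regions of 20 kb or wider, untreated libraries covered 93.5% and 90.1% of the bases and tamoxifen libraries 82.6% and 85.4%. The group means were 91.8% ± 2.38 and 84.0% ± 1.97 (SD, n = 2 each, two-sided exact permutation p = 0.333, the smallest possible). The lists themselves differed in peak width, with a median of 2511 bp untreated against 729 bp with tamoxifen in the first batch and 784 against 727 bp in the second (group means 1647.5 ± 1221 and 728 ± 1.41 bp, SD, n = 2 each, exact permutation p = 0.333). The narrowest 5% of peaks ended at 503 against 159 bp in the first batch and at 194 against 192 bp in the second. These regions were divided into 211 and 264 peaks in untreated cells and into 452 and 316 after tamoxifen. Coverage was lower with tamoxifen in 105 of the 112 regions within the first batch and in 88 within the second, and in 81 within both. Over the 497 kept regions of 10 kb or wider the means were 86.5% ± 1.75 and 79.3% ± 4.28 (n = 2 each, exact permutation p = 0.333). Of these 497, 433 were less covered with tamoxifen within the first batch and 314 within the second. Over all 4841 kept regions, untreated and tamoxifen libraries covered 80.5% and 65.8% of the bases in the first batch, and 74.35% and 74.44% in the second. Over kept regions as a whole, the drop was thus seen in the first batch alone. When regions were built from the second batch alone, the difference between tamoxifen and untreated coverage in regions of 20 kb or wider was -3.73 percentage points, against -7.85 over both batches.

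**Figure D4:**
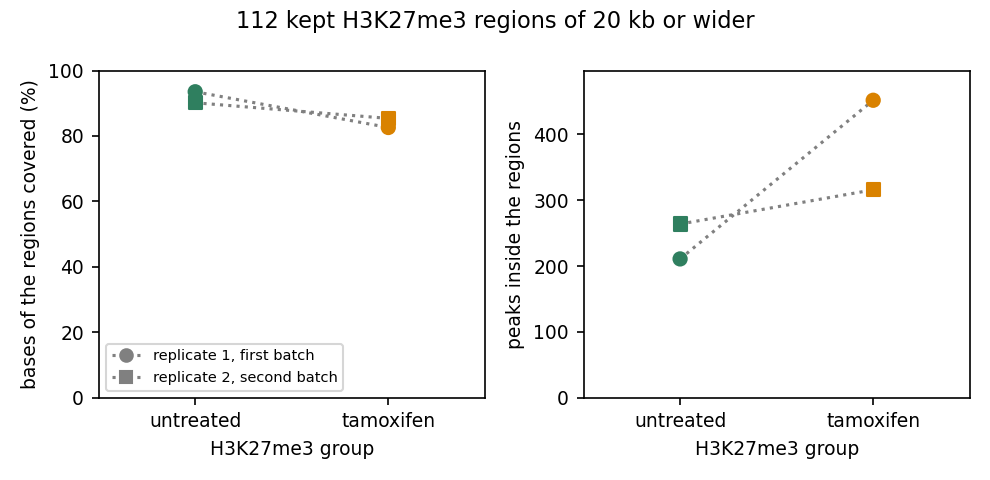
Share of bases covered (%) and number of peaks inside the 112 kept H3K27me3 regions of 20 kb or wider, in untreated and tamoxifen libraries. Circles are replicate 1 and squares replicate 2, and dotted lines join libraries of one batch. Coverage is lower after tamoxifen in both batches, at 82.6% against 93.5% and at 85.4% against 90.1%.

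Because Setdb1 methylates H3K9, the next comparison asked whether H3K27me3 appeared with tamoxifen where H3K9me3 lay in untreated cells. Few gained regions did. Of the 693 gained regions 5 overlapped the H3K9me3 consensus, which is 0.722% (95% Clopper-Pearson interval 0.235% to 1.68%), and of the 4841 kept regions 39 did, which is 0.806% (0.573% to 1.1%). The odds ratio was 0.895, with a 95% interval of 0.351 to 2.28 (two-sided Fisher's exact test p = 1.0). Gained regions overlapped H3K9me3 at 0.284 times the chance level of circular shifts (two-sided permutation p = 0.0012), and kept regions at 0.187 times (p = 0.0002, the smallest possible), and the difference between these was not tested. None of the 89 lost regions overlapped, where a count of 0 allows up to 3.37% and 2.39 ± 1.54 were found by chance (permutation p = 0.187). The intervals cover counting error alone. Settings with 1 library in a group gave other values, and their tests compare those libraries, not the treatments. Within the batches the odds ratios were 0.423 (Fisher's exact test p = 0.00149) and 0.576 (p = 0.00249). They were 0.570 without tamoxifen replicate 1 (Fisher's exact test p = 0.0113), 0.421 without tamoxifen replicate 2 (p = 0.00491), 1.14 without untreated replicate 1 (p = 0.671) and 0.768 without untreated replicate 2 (p = 0.532). Gained regions are narrower than kept ones. Over all 4 libraries, 3 of 329 gained and 0 of 18 kept regions under 1 kb overlapped (Fisher's exact test p = 1.0), 0 of 7 and 30 of 3711 did from 3 kb up, and from 1 to 3 kb, at 2 of 357 and 9 of 1112, the odds ratio was 0.690 (interval 0.148 to 3.21, Fisher's exact test p = 1.0), so these counts decide little within width classes. Within the batches, the odds ratio under 1 kb was 0.137 (0.0543 to 0.346) in the first and 0.488 (0.269 to 0.886) in the second, and from 1 to 3 kb it was 0.293 (0.0378 to 2.27) and 0.588 (0.242 to 1.43). Here too 1 list of each treatment is compared. Splitting by batch and width was added after the data were seen.

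Gained regions lay more often on chromosome 8 than kept ones, a comparison chosen after the data were seen. Chromosome 8 held 127 of 693 gained regions (18.3%) and 345 of 4841 kept regions (7.13%), an odds ratio of 2.92 with a 95% interval of 2.34 to 3.65 (Fisher's exact test adjusted p = 1.10e-17). It was the only one of 20 chromosomes past an adjusted p of 0.05 in this comparison, and 4 of the 10 widest gained regions lay on it. Of all peaks in a library, chromosome 8 held 11.2% and 10.5% with tamoxifen and 7.81% and 9.30% without it (exact permutation p = 0.333, n = 2 each, the smallest possible). With the 7041 widest peaks of each library these shares were 8.49% and 8.85% with tamoxifen and 7.81% and 7.87% without it. The 10 Mb from 120 to 130 Mb of chromosome 8 held 30 of the 127 gained regions, and without them and the kept regions there the odds ratio was 2.61 (interval 2.04 to 3.34). Regions found in a single library also lay on it more often than kept ones, at 18.1% and 11.6% for the tamoxifen libraries and 14.2% and 9.87% for the untreated ones. The odds ratio was 2.38 within the first batch and 1.41 within the second, and it was 1.79 without tamoxifen replicate 1.

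Chromosome 1 held 16 of the 89 lost regions (17.98%) against 6.34% of the kept ones, an odds ratio of 3.24 with an interval of 1.86 to 5.63 (Fisher's exact test adjusted p = 0.00346 over 20 chromosomes). Of regions found in a single library, chromosome 1 held 5.44% and 8.57% for untreated replicates 1 and 2. For tamoxifen replicates 1 and 2 it held 5.75% and 6.18%. Lost regions on it number under 20, and this comparison was also chosen after the data were seen.

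**Figure D5:**
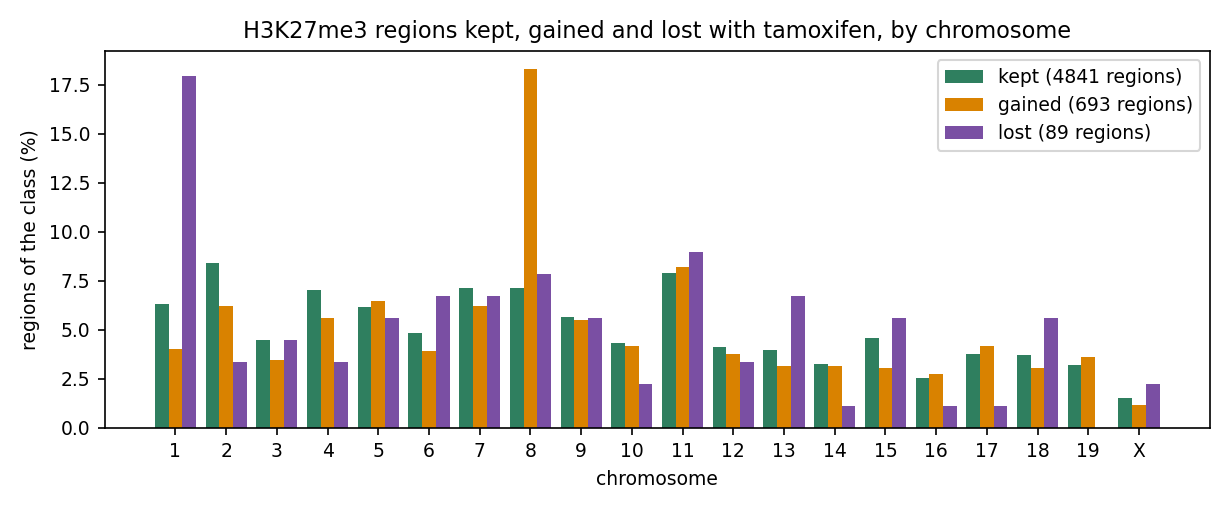
Share of the 4841 kept, 693 gained and 89 lost H3K27me3 regions (%) on each chromosome. Chromosome 8 holds 18.3% of gained and 7.13% of kept regions, and chromosome 1 holds 17.98% of lost and 6.34% of kept regions.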

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

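All tests of explanations in this part were chosen after the results were seen. In the H3K9me3 group, 27 measures were compared among the 4 libraries by the gap of the most distant library over the range, and 5 passed the 95% limit, where 1.35 are expected by chance. All 5 belong to replicate 1, the only H3K9me3 library of the first batch. Its median peak width was 1896 bp, against 806 to 830 bp in the other 3. Its share of peaks was higher on chromosome 7, at 6.34% against 5.20% to 5.33%, and on chromosome 14, at 5.01% against 4.49% to 4.52%. It was lower on chromosome 10, at 5.04% against 5.404% to 5.45%, and on chromosome 15, at 3.48% against 3.91% to 3.97%.

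The wide peaks of H3K9me3 replicate 1 were weighed against its processing. The older MACS2 version alone cannot be told apart from other causes. Of the 3 lists with that version, 2 were wider at the median than every list with the newer one. They were H3K9me3 replicate 1 and untreated H3K27me3 replicate 1, the latter at 2511 bp. The tamoxifen H3K27me3 list with the older version was at 729 bp, and the one with the newer version at 727 bp. The older version thus did not come with wide peaks in every list. Both wide lists also had few narrow peaks, with a 5th percentile of 330 and 503 bp against 159 to 197 bp in the other lists. Joining of neighbouring peaks over a longer distance is argued against, because the smallest gap between its peaks was 585 bp, shorter than the 693 to 705 bp of the other 3. The version, depth, enrichment and threshold may each contribute to the width and remain open, and no biological explanation was tested since the 4 libraries share a group.

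The chromosome 8 excess of gained H3K27me3 regions was set against 3 explanations. A local cluster of new peaks as the whole cause is argued against, because without the 10 Mb with most gained regions, from 120 to 130 Mb, the odds ratio was still 2.61 (95% interval 2.04 to 3.34), but in the second batch this stretch carried much of the excess of tamoxifen peaks on the chromosome, and without it the odds ratio of peaks there fell from 1.15 to 1.07 (interval 0.993 to 1.15), which leaves a local cluster open for that batch. A general excess of sparsely detected peaks stays open, because gained regions exceeded the other regions held by exactly 2 libraries with an odds ratio of 1.78 (1.42 to 2.22), but against the single pairs of libraries it was 2.63 (1.19 to 5.82) for the untreated pair, 1.90 (1.5003 to 2.395) for the second batch, 1.86 (0.8291 to 4.17) and 1.43 (1.05 to 1.96) for the crossed pairs and 1.41 (0.906 to 2.20) for the first batch, and 2 of these intervals reach 1. Extra copies of chromosome 8 in the tamoxifen cultures may also contribute and stay open, since, of the 13 bins of 10 Mb with at least 10 untreated peaks, 13 had a tamoxifen to untreated fold above that of the other chromosomes in the first batch (48.8% of bins elsewhere) and 10 in the second (42.04% elsewhere), where the excess outside 120 to 130 Mb did not pass the test, while the last, partial bin, with 4 and 3 untreated peaks, was not counted and lay below. A response of the whole chromosome to Setdb1 ablation stays open as well, and the inputs, which would show copy number, were not analysed here.

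H3K9me3 replicate 4 carries none as its antibody. A library made without antibody is argued against, because its Jaccard index was at least 0.498 with replicates 2 and 3, above the 0.478 of those with each other. A library of the other mark is argued against by an index of at most 0.00195 with any H3K27me3 library. An incomplete label is then a candidate explanation, and it was not tested in any other way.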

How the results depend on the processing

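The alternatives that rank peaks by width or leave out chromosome 8 or 1, and all alternatives of the chromosome 8 share and of the wide regions, were chosen after the data were seen. The deficit of H3K27me3 at the H3K9me3 consensus kept its direction and its side of the threshold in 10 of 10 alternatives, at 0.117 to 0.310 times chance. The chromosome 8 odds ratio kept its direction in 12 of 12, at 1.41 to 3.22. Some of these settings compare 1 list with 1 list, and all count regions as if they were independent. Against the same kept regions, those found in a single untreated library also gave odds ratios of 2.16 (replicate 1) and 1.43 (replicate 2). The count therefore does not tie the excess to the treatment. Peak numbers kept their direction in 8 of 8 alternatives for tamoxifen against untreated H3K27me3 and in 9 of 9 for the marks, in designs that cannot reach 0.05. Leaving out 1 library moved the first difference, 6623, to between 1596.5 (without untreated replicate 1) and 11649.5 (without untreated replicate 2). Mean overlap between libraries stayed within the spread of pairs in 3 of 3 alternatives for each of the 4 kinds of pair.

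The numbers of gained, lost and kept H3K27me3 regions, 693, 89 and 4841, depended on the setting. They were 431, 251 and 2501 where peaks had to cover 50% of a region, and 346, 16 and 2893 in the wider 50% of each list. With an equal number of widest peaks 128 were gained and 164 lost, and the batches alone gave 7351 and 742 in the first, and 12380, 7048 and 8968 in the second. Leaving out 1 library gave 892 to 11847 gained regions, the last without tamoxifen replicate 1, 245 to 6003 lost ones, the last without untreated replicate 1, and 4989 to 6371 kept ones. The ratio of gained to lost regions, 7.79, became 1.72 with 50% cover, 21.6 in the wider 50%, 0.780 with equal numbers and 1.76 in the second batch. It ranged from 0.149 without untreated replicate 1, where it reversed as with equal numbers, to 39.8 without tamoxifen replicate 1. Leaving out a library, or taking 1 batch alone, asks for fewer lists in each class. By construction this raises the counts of gained, lost and kept regions. For the other settings the cause was not tested.

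The odds ratio of gained against kept regions at H3K9me3 passed the threshold at 0.423 and 0.576 within the batches, where 1 list is compared with 1 list, and leaving out 1 library gave 0.421 to 1.14, past the threshold without tamoxifen replicate 1 (0.570) or 2 (0.421) and reaching 1.14 without untreated replicate 1. More regions are tested there than in the comparison of all 4 libraries. The other 13 of 17 alternatives did not pass. The coverage difference of wide kept regions, -7.85 percentage points, was -3.73 percentage points in the second batch. In 8 other alternatives it was -9.57 to -6.12 percentage points. These differ from -7.85 by less than 2.38 percentage points, the SD of the untreated libraries. The H3K9me3 consensus, 10815 regions, grew to 28675 when 2 libraries sufficed, and fell to 5336 in the wider 50% and 2835 with equal numbers. Leaving out 1 library gave 10986 to 19974, the last without replicate 1.

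The first library of each group carries no number, so nothing in the labels pairs the groups. A replicate block, which for H3K27me3 is the batch, chosen after the data were seen, left the mean difference in H3K27me3 peaks at 6623 ± 2053 (SD of 2 batches, sign-flip permutation p = 0.5, the smallest possible). Comparisons at transcription start sites and over gene lists, and alternatives that rank peaks by score, were not run, for lack of an mm9 annotation and of scores. Ranking by width favours the lists with wide peaks, untreated H3K27me3 replicate 1 and H3K9me3 replicate 1. Without read depth, the absence of a peak in 1 library is not evidence that the mark was absent.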

Other observations

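Regions found in a single H3K9me3 library had chromosome shares of their own. Chromosome X held 13.7% of the 3868 regions found in replicate 1 alone, against 2.01% of the consensus (odds ratio 7.72, 95% interval 6.56 to 9.09, Fisher's exact test adjusted p = 2.46e-149). It held 3.47%, 3.81% and 3.995% of those found in replicates 2, 3 and 4 alone. Chromosome 1 held 13.05% of the 4906 regions of replicate 4 alone, against 8.04% of the consensus. Chromosome 6 held 8.15% and 8.32% of the regions of replicates 2 and 3 alone, against 5.72%. For H3K27me3, chromosome 11 held 12.6% of the 2296 regions found in both second-batch libraries alone, against 7.91% of kept regions. These comparisons were chosen after the data were seen, and regions are not independent replicates.

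Peaks in regions shared by all libraries of their mark were wider than the other peaks in 8 of 8 libraries. The ratio of median widths ran from 1.84 in H3K9me3 replicate 1 to 4.46 in H3K27me3 tamoxifen replicate 2. Shared regions held 28.1% to 82.8% of a library's peaks, the highest share in untreated H3K27me3 replicate 1, which had the shortest list.

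The widest kept H3K27me3 regions may lie at the Hox clusters, whose homeobox genes pattern the body axis and are known Polycomb targets. This hypothesis was formed from the positions themselves, so their arrangement over chromosomes is not independent evidence for it. The 39 Hox genes in the GRCm38.p6 gene table lie on chromosomes 2, 6, 11 and 15, which held 7 of the 10 widest kept regions and 25.7% of all kept regions. Some of the 7 are neighbours, and the fifth widest lay on chromosome 2 at 40979310 bp from the fourth. Chromosomes alone cannot show whether a region lies at a cluster, so the hypothesis stays open without an mm9 annotation.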
